A study of Populus tremula x Populus alba with 12 samples.

How the data were processed

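Leaf RNA-seq of a hybrid poplar was analysed in 12 libraries of 4 genotype groups (knockout, intermediate phenotype, empty-vector and wild-type), 3 libraries each, grouped by the genotype given in the labels. Per the labels' protocols, RNA was extracted with phenol and chloroform from frozen leaf material, mRNA was enriched with a bead-based kit, and libraries were made with an Illumina RNA-seq kit. The values used were the counts deposited by the authors, 1 table per library, with a whole number for each of 16866 transcript rows of 16607 loci named by *Populus trichocarpa* type IDs. The submitters' processing notes name HISAT2, SAMtools, Cufflinks, HTSeq and DESeq2, without role or version; the genome build and the strand setting of the counting are not given in the sources used here. The sums of the columns differed between libraries and all values were whole, as for counts that were not normalised, and no row lacked a transcript ID. Rows were kept per transcript ID as listed, since 207 loci had more than 1 row.

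Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were filtered with filterByExpr on the 4 groups (minimum count 10, minimum total 15, proportion 0.7), which left 14279 rows with 99.8% of all counts. Libraries were scaled by TMM, and CPM values use the TMM-scaled library size. Group means were fitted to all 12 libraries together with 8 residual degrees of freedom and no covariate, since the labels give no batch, day or pairing. Each comparison was a two-sided quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over the tested rows and a threshold of 0.05 without a fold-change minimum. Controls were the average of the wild-type and empty-vector means. SEs of log2 fold changes were taken from the fold change and its F statistic, and 95% intervals from these SEs. They cover the spread between libraries; the floor of 3 counts, used where a group had 0 counts, covers counting error only.

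Total counts ranged from 5.38 to 17.3 M counts, with a median of 6.18 M. A floor of 3 counts equals 0.558 CPM in the shallowest library and 0.173 CPM in the deepest, and the common biological coefficient of variation was 24.6%. The test was tried on simulated counts with the control means, library sizes and trended dispersions of the real data and 200 changed genes among 14279. Transcripts were drawn independently, without variation that a library shares across them, so the rates below may be too favourable for the real libraries. Between knockout and controls it recovered 51% of genes changed 2-fold and 95% of genes changed 4-fold, and 5.81% of its calls fell on unchanged genes. Replicate pairs were compared with a chi-square statistic of their counts; the lowest value per degree of freedom was 9.54, so no library was treated as a duplicate.

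The files do not pair IDs with names, and an annotation was not used here. The design, the tests of the comparisons and lists, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 2 higher and 2 lower IDs with the largest fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the libraries compared. From each gene list it took up to 4 called members with a mean of at least 1 CPM, or the 2 most abundant where none was called. With an annotation the rule would have named more genes. Of 22 fixed lists, 17 were defined by description terms and could not be used without an annotation; 5 held published IDs, namely UDP-glycosyltransferases, salicinoid pathway enzymes, salicylic acid synthesis and signalling, phenylpropanoid and monolignol enzymes, and flavonoid and condensed tannin enzymes. Gene names of list members are published assignments recalled for these IDs and not checked against an annotation. The files held 1 of 1, 3 of 3, 1 of 3, 14 of 24 and 7 of 16 of the listed IDs. Genes named outside this rule (4CL5, F5H1, PAL3, PAL4, PAL5, the second benzoyltransferase and those of the closing section) were chosen after their values were seen, as were 2 further short lists, xylem secondary wall cellulose synthases and the sucrose transporter SUT4.

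Lists with at least 5 tested members were tested as sets with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, and with fry, adjusted over the lists within a comparison. The estimated correlation was 0.41 for the flavonoid and 0.58 for the phenylpropanoid list in knockout against controls. Fits with 1 library left out used only the preset one, so a list that passed in them has weak support. Principal components used log2 CPM with a prior count of 2. The effects of knockout and intermediate were compared with separate controls and against 100 simulations of unchanged groups. The alternatives were DESeq2-type size factors, upper-quartile scaling, no filter beyond 1 count, a filter of 10 counts in 6 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, either control genotype alone, and leaving out each library in turn. A fit without empty-vector libraries 1 and 3 was added after the data were examined. With upper-quartile scaling the share of higher calls was 53.2% for knockout against controls, where TMM gave 56.8%. For empty-vector against wild-type it was 100%, where TMM gave 83.3% of only 6 calls, so the latter shares rest on few calls.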

Results

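RNA of mature leaves was sequenced in 12 libraries of a hybrid poplar (*Populus tremula* × *P. alba*, labelled as an INRA hybrid clone). The leaves came from plants grown for 3 months in a greenhouse. The labels gave 4 genotype groups of 3 libraries each, namely knockout, intermediate phenotype (called intermediate here), empty-vector and wild-type. Total counts per library, in M counts, were 5.83, 5.38 and 9.20 in knockout, 5.87, 5.98 and 10.3 in intermediate, 9.77, 17.3 and 8.27 in empty-vector, and 5.45, 5.83 and 6.38 in wild-type. The 10 most abundant transcript rows held between 11.6% and 16.0% of a library's counts. Within a group, the correlation of log2 CPM across transcripts between library pairs ranged from 0.949 to 0.987, and no pair was as similar as sampling noise alone would make it. The labels do not say whether libraries of a group came from separate edited lines or from plants of 1 line, so the p-values measure the spread between these libraries.

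**Figure D1:**
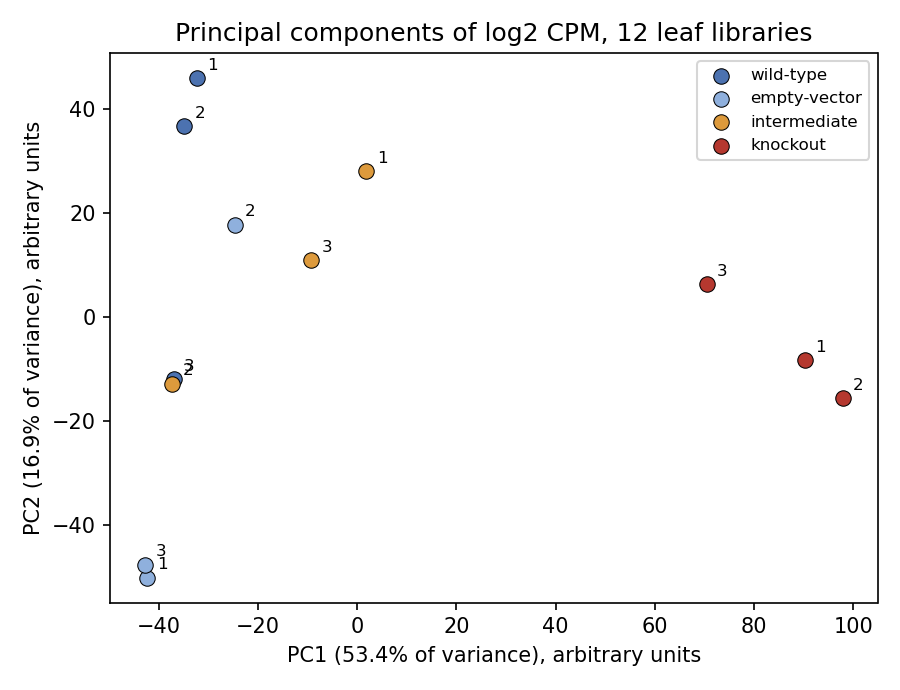
Principal components of log2 CPM over 14279 transcript rows; each point is 1 library, coloured by group and numbered by replicate, with both axes in arbitrary units. The 3 knockout libraries lie apart on the first component (53.4% of the variance), and control libraries of both groups are spread along the second (16.9%).

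The comparison of knockout with the 6 control libraries (wild-type and empty-vector) asked which leaf transcripts differed when a glycosyltransferase was disrupted by CRISPR. UGT71L1 (Potri.016G014500.1), a UDP-glycosyltransferase of the synthesis of salicinoids, the phenolic glycosides of poplar leaves, read 9.58, 11.2 and 10.1 CPM in the knockout libraries. It read 53.8, 38.9 and 34.6 CPM in wild-type and 36.5, 77.2 and 33.5 CPM in empty-vector. Its level was 4.44-fold lower in knockout (95% interval 2.74 to 7.19), a log2 fold change of −2.15 ± 0.30 (SE) with an adjusted p of 2.3e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not name the edited glycosyltransferase and small edits need not lower an RNA, so this level does not check the genotype labels. Related glycosyltransferases can share reads with UGT71L1 under the authors' counting, which leaves its exact level uncertain.

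Among the 3 measured genes of the salicinoid list, UGT71L1 fell, 1 benzoyltransferase rose and another did not pass the test. The benzoyltransferase Potri.019G043600.1, of a family that transfers benzoyl groups to alcohols, rose 8.20-fold (95% interval 5.54 to 12.1), from 66.2 ± 23.9 CPM in controls (SD, n = 6) to 541 ± 90.3 CPM in knockout (SD, n = 3), with an adjusted p of 4.2e-06 by edgeR's quasi-likelihood test. The second benzoyltransferase, Potri.013G074500.1, read 736 ± 112 CPM in knockout (SD, n = 3) and 468 ± 181 CPM in controls (SD, n = 6), with an adjusted p of 0.11 by the same edgeR test. Adjusted over the list alone, all 3 genes passed. NPR1 (Potri.006G148100.1), a receptor and coactivator of salicylic acid responses and the 1 measured gene of the salicylic acid list, was 2.32-fold higher in knockout (95% interval 1.72 to 3.12). Its level was 23.1 ± 4.63 CPM (SD, n = 3) against 10.1 ± 2.78 CPM in controls (SD, n = 6), and its adjusted p was 4.4e-04 by edgeR's test. The list of UDP-glycosyltransferases held 1 measured gene, UGT71L1.

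**Figure D2:**
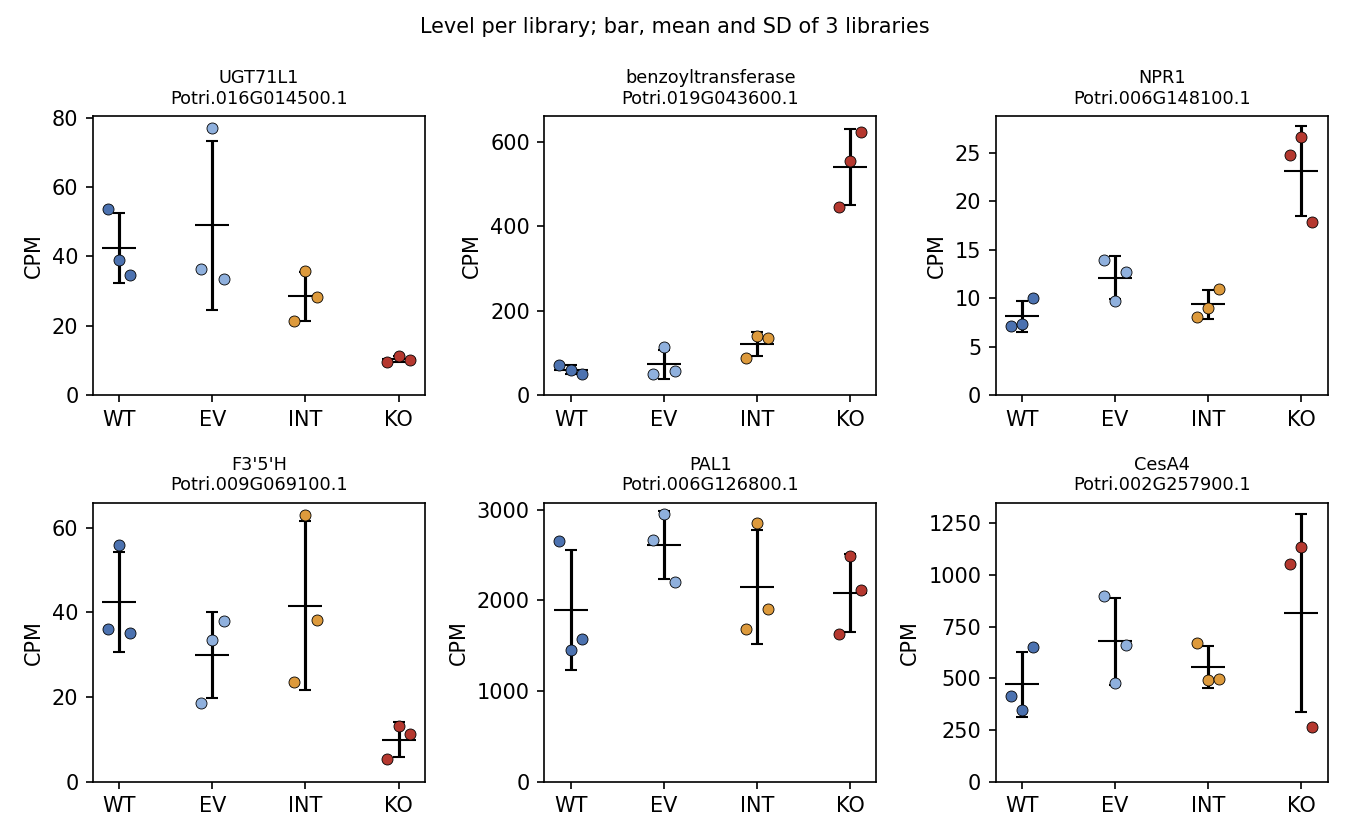
Level in CPM of 6 genes in each library; points are libraries, and the bar and whiskers are the mean and SD of the 3 libraries of wild-type (WT), empty-vector (EV), intermediate (INT) and knockout (KO). UGT71L1 and F3'5'H lie lower in every knockout library than in every control library, the benzoyltransferase and NPR1 lie higher, PAL1 overlaps between groups, and CesA4 is split within knockout.

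Of the 5 tested genes of the flavonoid and condensed tannin list, 2 were lower in knockout and 3 did not pass; adjusted over the list alone, 2 passed. The flavonoid 3',5'-hydroxylase F3'5'H (Potri.009G069100.1), which sets the hydroxylation of tannin units, was 3.55-fold lower (95% interval 1.95 to 6.50), at 5.47, 13.2 and 11.3 CPM in knockout and between 18.6 and 56.0 CPM in the controls. Its adjusted p was 0.0031 by edgeR's quasi-likelihood test. The flavanone 3-hydroxylase F3H (Potri.005G113900.1), an early step of the pathway, was 2.48-fold lower (95% interval 1.27 to 4.83; edgeR adjusted p = 0.032). This F3H call rested on empty-vector libraries 1 and 3, which read 471 and 240 CPM while the other 4 controls read 89.8 to 117 CPM. Without these 2 libraries the F3H log2 fold change was −0.61 (edgeR adjusted p = 0.13), against wild-type alone it was −0.62 (edgeR adjusted p = 0.33), and leaving out wild-type library 3 or any 1 knockout library also ended the call (edgeR adjusted p between 0.050 and 0.10). As a set, the flavonoid list did not differ from other genes (camera on limma-voom values, adjusted p = 0.30; adjusted p = 0.74 with an estimated correlation), but it passed without empty-vector library 2 (adjusted p = 0.047).

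The phenylpropanoid and monolignol list, the pathway from phenylalanine to lignin precursors, had 13 tested genes, and edgeR called 0 of them in knockout. At an unadjusted p under 0.05 there were 3, adjusted over the list alone there were 0, and DESeq2 and limma-voom called 0 each. PAL1 (Potri.006G126800.1), a phenylalanine ammonia-lyase at the entry of the pathway, read 2077 ± 431 CPM in knockout (SD, n = 3) and 2250 ± 620 CPM in controls (SD, n = 6), 1.07-fold lower with a 95% interval of 0.725 to 1.58 (edgeR adjusted p = 0.80). C4H2 (Potri.019G130700.1), the cinnamate 4-hydroxylase of the next step, had a log2 fold change of −0.15 ± 0.20 (SE; edgeR adjusted p = 0.60). Log2 fold changes in the list ran from −1.09 for 4CL5 (Potri.003G188500.1) to 0.50 for F5H1 (Potri.005G117500.1). The near-identical tandem genes PAL4 and PAL5 (Potri.010G224100.1 and Potri.010G224200.1) can share reads, so their values of 0.35 and 0.48 are uncertain. The list as a set did not pass (camera on limma-voom values, adjusted p = 0.35; adjusted p = 0.74 with an estimated correlation).

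Over all 14279 tested transcript rows, edgeR called 4296 (30.1%) between knockout and controls, 2439 higher and 1857 lower. Of these, 1387 were more than 2-fold higher and 1129 more than 2-fold lower. In 1958 of the higher and 1537 of the lower transcripts the 3 knockout libraries lay beyond all 6 controls. Chance gives this separation in 1.19% of unselected transcripts per direction. Called transcripts are selected for such a difference, so that share is no benchmark for them. Among called transcripts with a mean of at least 5 CPM and no overlap between the libraries compared, the largest rise was that of Potri.013G082700.1. It read 1445, 5843 and 682 CPM in knockout and at most 2.45 CPM in a control. Its log2 fold change was 11.40 ± 0.71 (SE, edgeR adjusted p = 6.8e-07). This value was 10.09 without knockout library 2, 12.32 against empty-vector alone and 10.49 against wild-type alone. Potri.003G190600.1 followed, at 84.2 ± 31.9 CPM in knockout (SD, n = 3) and 0.466 ± 0.465 CPM in controls (SD, n = 6), with a log2 fold change of 8.01, or 9.43 against empty-vector alone and 6.59 against wild-type alone. Potri.013G048200.1 had 0 counts in all knockout libraries and 8.32 ± 5.22 CPM in controls (SD, n = 6), which makes it at least 56.3-fold lower, taking a floor of 3 counts over the knockout group. Potri.010G208100.1 fell from 197 ± 99.3 CPM in controls (SD, n = 6) to 0.623 ± 0.162 CPM (SD, n = 3), with an edgeR adjusted p of 0.0016; without empty-vector libraries 1 and 3 its log2 fold change was −7.16 where all libraries gave −8.33, in limma-voom its adjusted p was 0.063, and the range over all its alternatives was 1.1e-12 to 0.063. The files do not pair these 4 IDs with names.

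**Figure D3:**
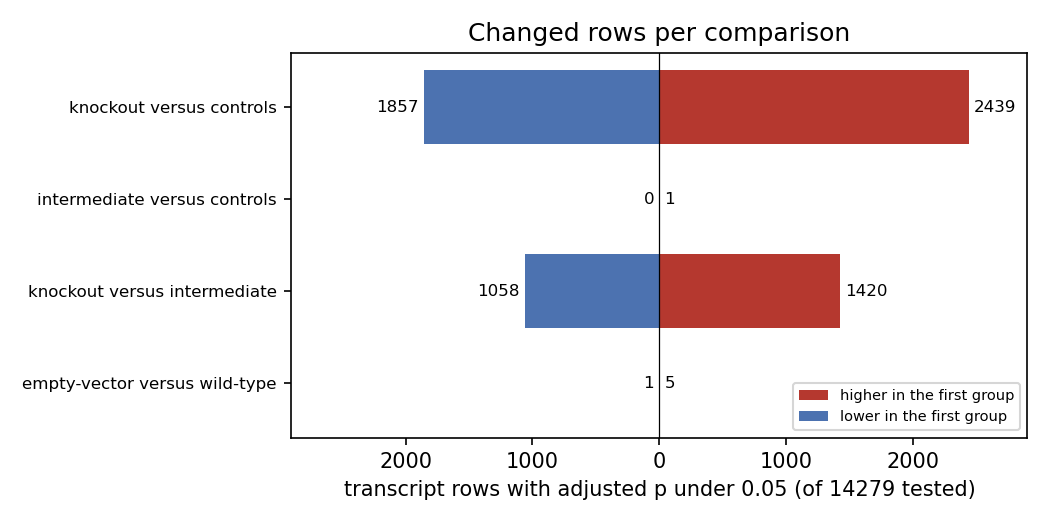
Number of transcript rows with an adjusted p under 0.05 in each comparison, of 14279 tested; bars to the right count rows higher in the first group named, bars to the left rows lower. Knockout differed from controls in 2439 and 1857 rows and from intermediate in 1420 and 1058, while the other comparisons held 1 and 6 rows.

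Knockout was next compared with the intermediate group, which the labels define only by an intermediate phenotype. UGT71L1 was 2.77-fold lower in knockout than in intermediate (95% interval 1.65 to 4.65; edgeR adjusted p = 0.0086), where it read 21.5, 35.7 and 28.2 CPM. The benzoyltransferase Potri.019G043600.1 was 4.48-fold higher (95% interval 2.75 to 7.29) and NPR1 2.45-fold higher (95% interval 1.71 to 3.51) in knockout, with edgeR adjusted p of 6.3e-04 and 0.0023. F3'5'H was 4.14-fold lower in knockout than in intermediate (95% interval 2.14 to 8.01; edgeR adjusted p = 0.0051). Of the salicinoid list 2 of 3 genes differed and of the flavonoid list 1 of 5; of the 13 phenylpropanoid genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Adjusted over the list alone, 2 salicinoid, 1 flavonoid and 0 phenylpropanoid genes passed. Neither larger list passed as a set (camera on limma-voom values, adjusted p = 0.65 for each; adjusted p = 0.85 for each with an estimated correlation).

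In all, edgeR called 2478 transcripts between knockout and intermediate, 1420 higher and 1058 lower in knockout. Among called transcripts with a mean of at least 5 CPM and no overlap between the libraries compared, Potri.013G082700.1 again had the largest rise. Its log2 fold change was 10.43 ± 0.94 (SE, edgeR adjusted p = 4.9e-05), or 9.11 without knockout library 2 and 11.15 without intermediate library 3. Potri.019G121800.1 was 75.6-fold higher (95% interval 35.0 to 163), at 3934 ± 1845 CPM in knockout and 52.1 ± 22.6 CPM in intermediate (SD, n = 3 each). Potri.013G048200.1, at 0 counts in knockout, was at least 28.2-fold lower by the same floor. It read 0.918, 8.18 and 3.39 CPM in the intermediate libraries, so this bound leans on library 2. Its edgeR call (adjusted p = 0.025) was lost in limma-voom (adjusted p = 0.11). It was also lost without intermediate library 2 or any 1 knockout library (edgeR adjusted p between 0.056 and 0.071). Potri.010G208100.1 was lower in knockout (log2 fold change −7.72, or −5.20 without intermediate library 2; edgeR adjusted p = 0.0055), a call lost in limma-voom (adjusted p = 0.21; range over all its alternatives 2.5e-08 to 0.21). The count fell to 1566 without intermediate library 2 and to 1607 without knockout library 2.

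The intermediate group was then compared with the 6 controls. UGT71L1 read 28.5 ± 7.12 CPM in intermediate (SD, n = 3) and 45.7 ± 17.1 CPM in controls (SD, n = 6), a log2 fold change of −0.68 ± 0.27 (SE) that did not pass over all genes (edgeR adjusted p = 0.69). The benzoyltransferase Potri.019G043600.1 read 121 ± 28.3 CPM (SD, n = 3; edgeR adjusted p = 0.41) and NPR1 9.34 ± 1.45 CPM (SD, n = 3; edgeR adjusted p = 0.999). Of the 3 salicinoid genes, 13 phenylpropanoid genes and 5 flavonoid genes, edgeR called 0, with 2, 1 and 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 of each; adjusted over the list alone, 2, 0 and 1 passed. The flavonoid list as a set had an adjusted p of 0.069 by camera (adjusted p = 0.44 with an estimated correlation). At the preset correlation, the only one run with a library left out, it passed by camera in 4 fits. These were without wild-type library 1 or 2, empty-vector library 2 or intermediate library 2 (adjusted p of 0.021, 0.025, 2.8e-04 and 0.0076). The phenylpropanoid list had an adjusted p of 0.34 (adjusted p = 0.73 with an estimated correlation) and passed only without intermediate library 2 (adjusted p = 0.033).

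Over all transcripts edgeR called 1 higher and 0 lower in intermediate, with 913 at an unadjusted p under 0.05 where chance gives 714, and DESeq2 called 63. The called transcript, Potri.008G135800.1, read 7.90, 12.0 and 8.48 CPM in intermediate and 3.15 ± 0.476 CPM in controls (SD, n = 6), a 3.02-fold rise (95% interval 2.23 to 4.09; edgeR adjusted p = 0.030). Its log2 fold change stayed between 1.39 and 1.73 over its alternatives, while its adjusted p ranged from 8.3e-07 to 0.29 and stayed under 0.05 when empty-vector library 2 was left out but not when any other of the 9 libraries was. It was also higher in knockout, at 5.53 ± 0.598 CPM (SD, n = 3; log2 fold change 0.82, edgeR adjusted p = 0.0084). In simulated libraries of these depths with 200 changed genes, the test recovered 55% of genes changed 2-fold and 96% of genes changed 4-fold between intermediate and controls. The simulation held no variation shared across transcripts of a library, so recovery in the real libraries may be lower.

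Empty-vector and wild-type, the control genotypes, were compared with each other. The flavonoid and condensed tannin genes were higher as a set in empty-vector (camera on limma-voom values, adjusted p = 0.032), a call that was lost with an estimated correlation (adjusted p = 0.33) and without wild-type library 3 (adjusted p = 0.076). By fry, which tests the set against no change and not against other genes, the adjusted p was 0.14. Of its 5 genes edgeR called 0, with 4 at an unadjusted p under 0.05, DESeq2 called 2, limma-voom called 0, and 4 passed adjusted over the list alone. F3H read 471, 96.9 and 240 CPM in empty-vector and 104 ± 13.6 CPM in wild-type (SD, n = 3; edgeR adjusted p = 0.21), so that 2 of 3 empty-vector libraries lay above wild-type. Of the 13 phenylpropanoid genes edgeR called 0, with 1 at an unadjusted p under 0.05; that gene, PAL3 (Potri.016G091100.1), read 1308 ± 330 CPM in empty-vector and 543 ± 109 CPM in wild-type (SD, n = 3 each; edgeR adjusted p = 0.17), and DESeq2 called 1, limma-voom called 0 and 1 passed adjusted over the list alone. The phenylpropanoid list as a set had an adjusted p of 0.17 by camera (adjusted p = 0.62 with an estimated correlation) and passed without empty-vector library 2 (adjusted p = 0.028). UGT71L1 and the other salicinoid genes gave 0 calls by edgeR, DESeq2 and limma-voom, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. NPR1 read 12.1 ± 2.20 CPM in empty-vector and 8.12 ± 1.59 CPM in wild-type (SD, n = 3 each, edgeR adjusted p = 0.25). Its unadjusted edgeR p was 0.029. Its list held 1 tested gene, so adjustment over the list alone leaves this p unchanged and adds no support.

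Over all transcripts edgeR called 6 between the control genotypes, 5 higher and 1 lower in empty-vector, with 2409 at an unadjusted p under 0.05, and DESeq2 called 239, 113 higher and 126 lower. Potri.010G010100.1 was 3.40-fold higher in empty-vector (95% interval 2.48 to 4.66; edgeR adjusted p = 0.015) and Potri.012G027200.1 3.21-fold higher (95% interval 2.28 to 4.52; edgeR adjusted p = 0.028). Potri.006G071500.1 was 2.19-fold lower (95% interval 1.69 to 2.85; edgeR adjusted p = 0.046). These 3 transcripts kept their direction throughout but passed in 9, 8 and 7 of 14 alternatives, with adjusted p up to 0.516, 0.691 and 0.998. With upper-quartile scaling edgeR called 3 higher and 0 lower. The number of calls rested on single libraries: it was 1302 without empty-vector library 2 (375 higher and 927 lower) and 17 without wild-type library 3, 1 without wild-type library 2, and 0 without wild-type library 1, empty-vector library 1 or empty-vector library 3.

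The effects of knockout and intermediate were compared across transcripts, which are not independent replicates. With knockout set against empty-vector and intermediate against wild-type, so that no control was shared, the log2 fold changes had a Pearson correlation of 0.365 and a covariance of 0.141. With the controls exchanged the correlation was 0.226 and the covariance 0.109. Against all 6 shared controls the correlation was 0.546 and the covariance 0.186, where 100 simulations of unchanged groups gave means of 0.322 and 0.029 from the shared controls alone. The correlation with separate controls was 0.171 without intermediate library 1 and 0.230 without wild-type library 3.

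**Figure D4:**
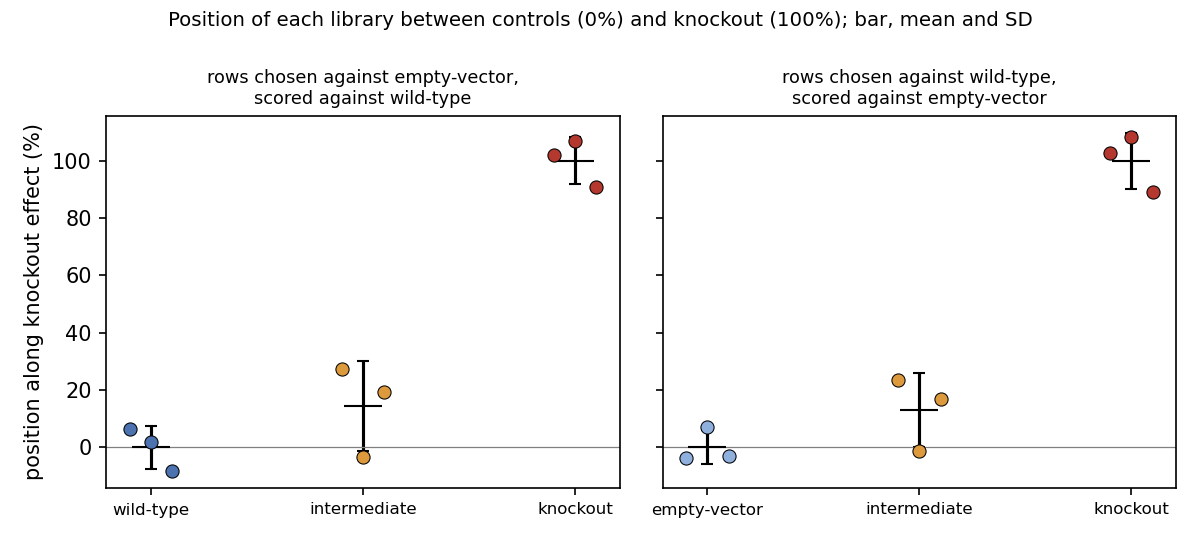
Position of each library along the knockout effect, in percent, where 0% is the mean of the control group scored and 100% the knockout mean. Each control library was instead set against the mean of the other libraries of its group, which widens the spread of the control points. Points are libraries and the bar and whiskers the mean and SD of 3. Transcripts were chosen against one control genotype and scored against the other, and intermediate libraries 1 and 3 lie between 17.0% and 27.3% in both panels while library 2 lies at −3.21% and −1.44%.

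The position of each library along the knockout effect was scored on transcripts called against one control genotype, with the other as the baseline. A control library was set against the other libraries of its group, so control scores average 0 by construction and are spread wider. The permutation tests used these scores. On the 3557 transcripts called against empty-vector and scored against wild-type, intermediate libraries stood at 27.3%, −3.21% and 19.1% of the knockout effect, and wild-type libraries at 6.28%, 1.996% and −8.27%. The difference between the groups gave p = 0.3 by a two-sided exact permutation test (n = 3 each), where 0.1 is the smallest p possible. With the control genotypes exchanged, intermediate libraries stood at 23.6%, −1.44% and 17.0% on 3902 transcripts and empty-vector libraries at −3.71%, 6.92% and −3.21% (p = 0.2, two-sided exact permutation test, n = 3 each).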

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

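Among the tests here, the mixing test, the comparison with UGT71L1 levels and the shuffles of gene order were chosen only after the result was seen. The thinning and the removal of transcripts were set up for a control split already found, but before their own outcome was seen. The other tests were not chosen after a result was seen.

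The effects of knockout and intermediate against the same controls differed in 2478 transcripts by edgeR's quasi-likelihood test of the difference itself. The shared controls cancel in this difference, so it is the comparison of knockout with intermediate given above and no second result. In the salicinoid and salicylic acid lists the knockout minus intermediate difference, on the log2 scale, was −1.47 for UGT71L1, 2.16 for the benzoyltransferase Potri.019G043600.1 and 1.29 for NPR1. It was −2.05 for F3'5'H of the flavonoid list and 0.56 for SUT4 (Potri.002G106900.1), a sucrose transporter named after its values were seen. Among IDs without names it was 10.43 for Potri.013G082700.1, 5.27 for Potri.003G190600.1, 6.24 for Potri.019G121800.1, −7.72 for Potri.010G208100.1 and −0.77 for Potri.008G135800.1. Potri.013G048200.1 was at least 28.2-fold lower in knockout, a bound that leans on intermediate library 2 (8.18 CPM). Its call was lost without that library. In limma-voom the calls of Potri.010G208100.1 and Potri.013G048200.1 were lost (adjusted p of 0.21 and 0.11). The real split of these 6 libraries gave 2478 calls and the highest other split 9, and 1 split of 10 gave as many, but 10 splits are too few for a share under 0.05.

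Intermediate libraries 1 and 3 stood at 17.0% to 27.3% of the knockout effect and library 2 near 0, although 1 transcript was called in the group. With separate controls the covariance of the effects was 0.141 and, exchanged, 0.109, which argues against the sharing of control libraries as its whole source. The highest of 100 simulations of unchanged groups was 0.0025, but these drew each transcript independently. They hold no variation that a library shares across transcripts, so they cannot exclude chance differences between plants. By library, the two-sided exact permutation test of the shift gave p = 0.3 and 0.2 (n = 3 each). Knockout RNA mixed in at one share would give the same share in all transcripts. For those over 32-fold higher in knockout, the median rise over wild-type was 0.701% of the knockout's rise in library 1 and 1.08% in library 3. For 2- to 4-fold transcripts it was 13.9% and 14.3%, ratios of 0.0505 (95% bootstrap interval over transcripts −0.0075 to 0.098) and 0.0753 (0.023 to 0.202). Library 2, which stood near 0, had 0.312% and 6.11%, a ratio of 0.0511 (−0.018 to 0.151). A low ratio thus also arose without a shift, and no control library was scored this way. The ratios alone are therefore weak evidence. Mixing at 13.9% or 14.3% would, however, give that same share in the 42 transcripts over 32-fold. Their medians of 0.701% and 1.08% argue against mixing of that size in libraries 1 and 3. A share of 1.08% or less stays open. A graded response to a partial loss of the glycosyltransferase may be a cause and stays open. Of the intermediate libraries, that with the largest shift had the lowest UGT71L1 level, 21.5 CPM. The others had 28.2 and 35.7 CPM in order of smaller shifts, but 3 libraries cannot test an order. Wild-type libraries ran the other way: 53.8, 38.9 and 34.6 CPM went with positions of 6.28%, 1.996% and −8.27%. Empty-vector libraries at 36.5, 77.2 and 33.5 CPM stood at −3.71%, 6.92% and −3.21%. UGT71L1 belongs to the transcripts that define the shift, and unrecorded differences between plants also remain open.

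A split of the 6 control libraries that crosses their genotypes (empty-vector 1 and 3 with wild-type 3, against wild-type 1 and 2 with empty-vector 2) called 1951 transcripts, while empty-vector against wild-type called 6. This points to a structure of the samples that the labels do not record. Depth as the whole cause is argued against by libraries thinned to 5.38 M counts, in which the split still called 1736. Without the 10 most abundant transcripts and 50 of the most variable chromosome window it called 1874. Removing so few transcripts could not directly take away most of the calls. The value shows only that the calls were not confined to them, and draws no conclusion on a cause. A batch, a harvest time or the position in the greenhouse could be behind this split and stay untested, since no label gives one. No biological explanation was tested.

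Transcripts called in knockout lay next to each other more often than random placement gives: 944 neighbouring pairs were called in the same direction among 13630 ordered loci, where 1000 shuffles within chromosomes had a mean of 630 and a highest value of 688. The longest runs held 8 loci, 1 lower on chromosome 17 (median log2 fold change −5.05) and 1 higher on chromosome 19 (median 1.32), with positions and chromosomes read from the order of the IDs. Loss or gain of a long chromosome segment stays open: the lowest median of any 50-locus window in a knockout library was −0.735, in library 2, and the highest 0.732, in library 1, both beyond the range of −0.5 to 0.4 set as evidence against it, while control libraries also differ by as much in a window on chromosome 13. Tandem copies that are regulated together or share reads may be another source, untested without an annotation. No biological explanation given by the design was tested.

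Regrouping tests bore on the other comparisons as well. For knockout against controls, treated as 1 group, the real split called 4011 and 1 of 84 splits gave as many, the highest other calling 1514. Chance is therefore unlikely at this number of splits, but regrouping does not exclude an unrecorded structure of the samples. For intermediate against controls, 6 of 84 splits called as many as the real 1, the highest 1463, so chance is not excluded. For empty-vector against wild-type, 2 of 10 splits called as many as the real 6, the highest 1951, and 10 splits are too few for a share under 0.05.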

How the results depend on the processing

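The fit without empty-vector libraries 1 and 3 was chosen after the result was seen; the other alternatives were not. Knockout against controls gave between 3086 and 4836 calls under every alternative run, within 1.5 times of 4296, and UGT71L1, the benzoyltransferase Potri.019G043600.1, NPR1, F3'5'H, Potri.003G190600.1 and Potri.013G048200.1 kept their direction and their calls in all 19 alternatives. Potri.013G082700.1 did so in the 18 in which it was tested; the filter of 10 counts in 6 libraries removed it. Knockout against intermediate gave 1566 to 2642 when 1 library was left out. Intermediate against controls gave 1 call, and 2 without a filter, 63 in DESeq2, 18 against empty-vector alone, 0 against wild-type alone, 0 with only the groups compared, 0 without empty-vector libraries 1 and 3, and 0 to 3 with 1 library left out. Empty-vector against wild-type gave 6 calls, and 3 with upper-quartile scaling, 239 in DESeq2 (6537 adjusted p values were NA), 0 with only the groups compared, 0 without empty-vector libraries 1 and 3, and 0 to 1302 with 1 library left out. Fewer libraries enter the last 3 kinds of fit; for the other settings the cause was not tested. The correlation of the knockout and intermediate effects, 0.365, was 0.226 with controls exchanged, 0.546 with shared controls, which add correlation by construction, and 0.171 to 0.496 with 1 library left out. Of uncalled genes near 0, PAL1 turned to 0.134 against wild-type alone and ran from −0.243 to 0.061 with 1 library left out, CesA7-B (Potri.018G103900.1) turned to −0.054 against empty-vector alone and ran from −0.144 to 0.571, and C4H2 turned to 0.037 without empty-vector libraries 1 and 3. The direction of a list turned in some fits with 1 library left out, with adjusted p from camera of 0.086 to 0.578 (phenylpropanoid, knockout against controls), 0.033 to 0.998 (phenylpropanoid, intermediate against controls), 0.164 to 0.916 and 0.409 to 0.994 (phenylpropanoid and flavonoid, knockout against intermediate) and 0.028 to 0.989 (phenylpropanoid, empty-vector against wild-type); the cause was not tested. Of the other values for named genes, 328 kept direction and side of the threshold, 44 lost the call and 1 gained it. Depth limits transcripts near the floor of 3 counts, 0.558 CPM in the shallowest library.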

Other observations

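The genes of the next 2 paragraphs and their tests were chosen after their values were seen. SUT4 (Potri.002G106900.1), a sucrose transporter of the vacuole membrane, was 1.45-fold higher in knockout than in controls (95% interval 1.16 to 1.81), at 244, 211 and 182 CPM against 115 to 188 CPM in the 6 control libraries (edgeR adjusted p = 0.011). Against empty-vector alone its log2 fold change was 0.35 (edgeR adjusted p = 0.14), without knockout library 1 it was 0.43 (edgeR adjusted p = 0.075), and over all its alternatives the adjusted p ranged from 0.0014 to 0.14. CesA4 (Potri.002G257900.1), a cellulose synthase of the secondary walls of xylem, read 1053, 1134 and 268 CPM in the knockout libraries and 576 ± 202 CPM in controls (SD, n = 6; edgeR adjusted p = 0.31). Without knockout library 3 its log2 fold change was 0.90 with an edgeR adjusted p of 0.018, the only 1 of its alternatives that passed (range 0.018 to 0.76). CesA7-B (Potri.018G103900.1) read 347, 391 and 87.9 CPM in knockout, and the ferulate 5-hydroxylase F5H2 (Potri.007G016400.1) of syringyl lignin read 75.4, 156 and 13.2 CPM. The third measured xylem cellulose synthase, CesA8-A (Potri.011G069600.1), read 1.88, 2.24 and 1.10 CPM in knockout and 0.384 to 2.85 CPM in the other 9 libraries. Of the 3 measured xylem cellulose synthases edgeR called 0 in each comparison, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom.

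Of the flavonoid and condensed tannin list, 4 genes picked because they were high in empty-vector libraries 1 and 3 are given here, without a test of this grouping. The anthocyanidin synthase gene LDOX (Potri.001G113100.1) read 1368 and 301 CPM in them and 6.47 to 85.8 CPM in the other 10 libraries. MYB115 (Potri.002G173900.1), an activator of tannin synthesis, had 400 and 78 counts in these 2 libraries and at most 8 in any other. The related activator MYB134 (Potri.006G221800.2) read 26.0 and 19.5 CPM in them and at most 10.1 CPM elsewhere, and the flavonoid 3'-hydroxylase F3'H (Potri.013G073300.1) read 191 and 62.1 CPM and at most 32.7 CPM elsewhere. Between empty-vector and wild-type none of the 3 tested genes passed (edgeR adjusted p of 0.16, 0.21 and 0.19 for LDOX, MYB134 and F3'H; MYB115 was below the filter). F3'5'H of the same list was not high there, at 18.6 and 37.9 CPM in these 2 libraries and 33.6 to 56.0 CPM in the other 4 controls.

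Potri.002G223900.1, chosen after its values were seen, was read only in empty-vector libraries, at 5.12, 6.58 and 6.83 CPM (232 counts), and had 0 counts in the other 9 libraries, where 364 would be read at that level. It was at least 35.7-fold higher in empty-vector than in wild-type, with a floor of 3 counts over the wild-type group (edgeR adjusted p = 0.046). It was the 1 transcript with at least 3 counts in each library of the group and 0 in all others, and of the 220 possible sets of 3 libraries 3 had as many such transcripts or more, the highest 5.

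The 20 tested loci nearest to UGT71L1 in ID order had a median log2 fold change of 0.31 in knockout, with 7 called higher and 3 lower. The second principal component and the log10 total count had a Pearson correlation of −0.143 (permutation p = 0.66) and a Spearman correlation of −0.168 (permutation p = 0.60) over 12 libraries; without the 2 libraries farthest from the median total, Pearson's r was −0.592.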
